A study of Mus musculus with 6 samples.

How the data were processed

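Poly(A)-selected RNA from BV2 cells, an immortalised mouse microglial line, was sequenced in 6 libraries. The labels put 3 libraries in a group overexpressing GFP, the control protein, and 3 in a group overexpressing TDP43-NLS, a TDP-43 construct that the series' design text describes as mutated in the nuclear localisation signal. The labels number the libraries 1 to 3 within each group and do not say whether they came from separate cultures, so every p-value measures the spread between these samples, which may be technical. The libraries, per the labels' protocols, were made with a NEBNext Ultra RNA kit with no strand-marking step described, and whether the counting used strand is not given in the sources used here.

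Counts and FPKM values were used. The deposited count table holds whole-number reads per gene for 55359 mouse genes, and 25032 of these have at least 1 read in some library. No row of it lacks a gene. The deposited FPKM table holds length- and depth-scaled values for the same 25032 genes, with the position and annotation of each gene. A length for each gene was derived from its deposited counts and FPKM values and the column totals. FPKM values recomputed with it differed from the deposited ones by a relative 4.44e-16 at most. The ratio of FPKM to depth-scaled count was thus the same in every library. The FPKM values are therefore a rescaling of the counts and not a second measurement. For a gene read in only 1 library this holds by construction. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq 0.6.0 and Bowtie2 2.2.3 were used with the mouse build GRCm39, and the notes as used here give neither their roles nor their order. The treatment of reads that match several genes is not given in the sources used here. Values of near-identical genes (the H2 genes, Oas1, Ifi20x, Slfn and Trim30 families, Bglap2, histones and ribosomal proteins) and of overlapping or antisense genes are therefore uncertain. Positions are those of the deposited annotation, on GRCm39, counted from 1. The reference in hand was of the earlier mouse build and gave only the GC content of transcripts.

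Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr at its default of 10 reads and 15 in total, which left 13199 genes. Libraries were scaled by TMM, and the quasi-likelihood test was run two-sided with the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen in the libraries labelled TDP43-NLS. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are reads of a gene relative to its library's total after TMM scaling, as mean ± SD over 3 libraries. Where the 3 libraries of a group held no read of a gene, the fold is a lower bound against 3 reads over the whole group, and where they held 1 to 3 reads it is a ratio with its 95% exact binomial interval. Such intervals and floors cover counting error only.

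Before the data were examined, 34 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, and adjusted over the 27 lists that qualified. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list change at all, without comparing them with other genes. The terms of the deposited Gene Ontology annotation with 10 to 500 tested genes were tested one-sided with Fisher's exact test, for higher and lower genes apart, against tested genes that carry any term. The FPKM values were tested as log2(FPKM + 1) with limma's trend method after removing genes with a mean under 0.5, as a check of the count result. Median fold changes by chromosome used genes above an average log2 CPM of 3, and 10000 shuffles of genes over chromosomes gave the permutation p of the largest deviation.

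The named genes are Tardbp and 6 genes of necroptosis signalling whatever their result. They also include the 10 genes with the largest fold change each way among called genes with a mean of at least 1 CPM, no overlap between the groups and an established symbol. From each list with a call come up to 4 called members with the smallest adjusted p. Some genes that this rule names are not reported here. Other genes named in the text were chosen after their values were seen, and are said to be so.

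The totals ran from 15062131 to 18005592 reads per library. Counts were simulated for the 13199 genes from the means, library sizes and dispersion of this comparison, with a small part of the genes changed. Of the changed genes, 58% of those changed 1.25-fold, 89.8% of those changed 1.5-fold and 90% of those changed 2-fold were recovered. All of those changed 4-fold (100%) were recovered. There were 12 false calls, and 0 calls when no gene was changed. A planted list, a planted term and a planted chromosome were also recovered. Far fewer genes were changed than were called in the real data, and genes were simulated independently of each other. These shares need not hold for the real data, and the planted list does not test camera where genes are correlated. Alternatives covered the scaling (RLE, upper quartile, library totals), the test (DESeq2 1.42.0, limma-voom, a test against a log2 fold change of 0.5), the filter, the replicate number as a block, and each library left out. No library or column in hand was set aside, and genes were left out only by these filters.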

Results

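Gene expression was measured by RNA sequencing in BV2 cells, an immortalised line of mouse microglia, the resident macrophages of the brain. The series' title places the study in microglial necroptosis, a regulated lytic form of cell death, and its comparison asks what changes in cells given TDP-43 with a disabled nuclear localisation signal relative to cells given GFP. TDP-43 is an RNA-binding protein that is mostly nuclear in healthy cells. There were 3 libraries labelled GFP, with 15361351, 16666112 and 17367688 counted reads, and 3 labelled TDP43-NLS, with 15062131, 18005592 and 17611814. Mitochondrial genes took 1.55% ± 0.0641 of the reads in the GFP group and 1.54% ± 0.119 in the TDP43-NLS group (SD, n = 3 each). The 10 most abundant genes took 5.28% ± 0.0432 and 5.86% ± 0.0797.

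The groups were far apart. The first principal component of log2 CPM held 85.8% of the variance and separated the groups, and Spearman correlations across genes were at least 0.996 within a group against 0.971 to 0.972 between groups. The second component, with 5.01% of the variance, set GFP replicate 2 apart from the other GFP libraries. No libraries of a group differed by so little that they could be the same library deposited again. The closest pair, GFP replicates 1 and 3, still had a chi-square per degree of freedom of 1.20 over 12925 genes.

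Tardbp, the mouse gene for TDP-43 (ENSMUSG00000041459, chromosome 4, 148696839 to 148711476, minus strand), was lower in the libraries labelled TDP43-NLS. It had 7229, 7160 and 8154 reads in the GFP libraries and 5671, 6506 and 6633 in the TDP43-NLS libraries. This is 451 ± 24 CPM against 377 ± 9.62 CPM (SD, n = 3 each), a log2 fold change of -0.26 with a standard error of 0.05 and an adjusted p of 0.000269 in edgeR's quasi-likelihood test, lower in 3 of 3 libraries. The call ended when the test was set against a log2 fold change of 0.5. The labels do not give the species of the construct, and no row of the count table is a construct or GFP, so the overexpression itself was not measured here. Because the targeted gene went against its label, the groups are called by their labels throughout, and every direction below rests on those labels.

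A large part of the expressed genome differed. Of 13199 tested genes, 3872 rose and 3733 fell in the libraries labelled TDP43-NLS, which is 57.6% of them. Most changes were small: 4389 of the 7605 called genes had an absolute log2 fold change under 0.5. At a log2 fold change of at least 1, 836 genes rose and 488 fell, and tested against a log2 fold change of 0.5, 1226 rose and 749 fell. In 63.2% of the tested genes the groups did not overlap, where chance gives 10%. The biological coefficient of variation was 4.62%, so the test reached small changes.

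The 10 genes with the largest increases under the rule for named genes were hardly expressed in the GFP libraries, and they include inflammatory mediators. Nos2, the inducible nitric oxide synthase, stood at 0.235 ± 0.152 CPM in the GFP group and 219 ± 9.17 CPM in the TDP43-NLS group (SD, n = 3 each), a log2 fold change of 9.79 (standard error 0.12, adjusted p = 2.58e-14). Csf3, the granulocyte growth factor, had 1 read in the GFP group and 695 in the other, a ratio of 695 with an interval of 124 to 27480. Il6, a pro-inflammatory cytokine, had 2 and 236 reads, a ratio of 118 with an interval of 32.3 to 980. Cxcl2, a neutrophil-attracting chemokine, rose from 0.139 to 16.5 CPM (log2 fold change 6.81). Serpinb2, a plasminogen activator inhibitor, and Ppfibp2, a liprin scaffold protein, had no read in the GFP libraries and were at least 41.3-fold and 89.6-fold higher. Cfap69, Ceacam19 and Serpinb10 rose by log2 fold changes of 6.73, 6.71 and 5.83.

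Strong decreases were of another kind. Adrb1, the beta-1 adrenergic receptor, and Slc9a7, a sodium-proton exchanger, had no read in the TDP43-NLS libraries and were at least 43.3-fold and 39.0-fold lower. Cxcr4, the receptor for the chemokine Cxcl12, fell from 24.3 ± 1.44 to 0.485 ± 0.183 CPM (SD, n = 3 each, log2 fold change -5.64, standard error 0.16, adjusted p = 1.30e-11). Iqgap2, a scaffold of the actin cytoskeleton, fell from 66.9 to 1.48 CPM (log2 fold change -5.49), and Asb10 from 34.1 to 0.868 CPM (log2 fold change -5.26). Sema5b, a semaphorin, fell by 6.06 on the log2 scale and lies on chromosome 16, whose genes were lower as a group. Bglap2, Gatm and Mgst1 had 2, 2 and 3 reads in the TDP43-NLS libraries against 130, 123 and 115, ratios of 65.0 (interval 17.6 to 543), 61.5 (16.7 to 514) and 38.3 (12.8 to 189).

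The necroptosis list rose, and most of its size came from the kinase Ripk3 and the cytokine Tnf. Ripk3 (ENSMUSG00000022221, chromosome 14, 56022452 to 56026322, minus strand), the kinase that phosphorylates Mlkl, had 4, 4 and 4 reads in the GFP libraries and 209, 299 and 243 in the TDP43-NLS libraries. In CPM this was 0.241 ± 0.0152 against 15 ± 1.59 (SD, n = 3 each), a log2 fold change of 5.92 with a standard error of 0.20 and an adjusted p of 7.37e-11. Mlkl, whose product permeabilises the membrane in necroptosis, rose from 61.1 ± 0.778 to 88.2 ± 1.23 CPM (log2 fold change 0.53, standard error 0.04, adjusted p = 3.49e-07). Tnf rose from 31.5 ± 4.30 to 264 ± 5.27 CPM (log2 fold change 3.07), Ticam1, the Toll-like receptor adaptor TRIF, from 16.3 to 32.2 CPM (log2 fold change 0.98), and Casp8, the protease that restrains necroptosis, from 79.7 to 93.6 CPM (log2 fold change 0.23). Ripk1, the upstream kinase, had 64.5 ± 1.91 and 60.7 ± 3.89 CPM (log2 fold change -0.09, adjusted p = 0.195). Zbp1, a nucleic acid sensor that can also start necroptosis, had 5 reads in all GFP libraries and 1 in all TDP43-NLS libraries and was not tested. Of 19 tested members 11 rose, 3 fell and 5 were not called (12 rose and 4 fell when adjusted over the list alone), with a median log2 fold change of 0.21. The list passed camera (adjusted p = 0.00502), and had an adjusted p = 0.137 with an estimated correlation. Ticam1 lies in the distal part of chromosome 17, whose genes were higher as a group. Tested against a log2 fold change of 0.5, Mlkl (adjusted p = 0.464) and Casp8 (adjusted p = 1) lost their calls.

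**Figure D1:**
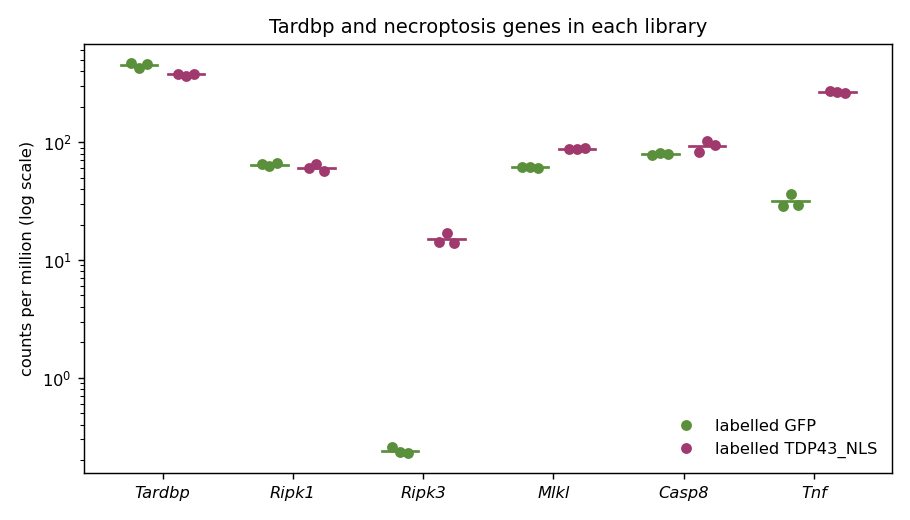
CPM of Tardbp and 5 necroptosis genes in each library on a log axis, with a point per library, a bar at the mean of each group, and the groups named by their labels. Ripk3 stood at 0.228 to 0.258 CPM in the GFP libraries and at 14 to 16.8 CPM in the libraries labelled TDP43-NLS, while Ripk1 overlapped between the groups.

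NF-kB-driven inflammatory genes were the most strongly raised list. Of 36 tested members 30 rose and 2 fell (the same numbers when adjusted over the list alone), with a median log2 fold change of 1.35. Besides Nos2, Ccl7 and Ccl2, chemokines for monocytes, rose by log2 fold changes of 5.59 and 3.09, and Nfkbiz, a nuclear regulator of NF-kB, rose by 3.21 although it lies on chromosome 16, whose genes were lower as a group. The camera adjusted p was 7.61e-52, and this was the only list still called with an estimated correlation (adjusted p = 0.00563). Immediate early genes, which respond to growth factor and stress signals, also rose, with 21 higher and 4 lower of 26 (adjusted over the list alone the same, median log2 fold change 0.67, camera adjusted p = 6.53e-09, adjusted p = 0.0869 with an estimated correlation). The most significant of them were feedback inhibitors of MAP kinase signalling and a survival gene: Ier3 rose by 2.87, Dusp5 by 1.99, Spry4 by 1.70 and Dusp6 by 1.21 on the log2 scale.

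Type I interferon-stimulated genes rose on balance but not as a block. Of 57 tested members 38 rose and 8 fell (the same when adjusted over the list alone), with a median log2 fold change of 0.44, a camera adjusted p of 1.07e-07 and an adjusted p = 0.0898 with an estimated correlation. Ifitm3, which blocks viral entry, rose from 15.9 to 223 CPM (log2 fold change 3.80), Irf7, a transcription factor of the interferon response, rose by 1.45 and Oas3, a sensor of double-stranded RNA, by 1.07. Trim30a, a regulator of Toll-like receptor signalling, fell by 2.60. The MHC class I and antigen processing list had 16 genes higher and 1 lower of 21 (the same adjusted over the list alone; median log2 fold change 0.51, camera adjusted p = 0.000628, adjusted p = 0.169 with an estimated correlation). H2-K1 rose by 1.09, H2-T23 by 1.12, B2m, the light chain of class I molecules, by 0.72, and Nlrc5, their transcriptional activator, by 0.71. The class II list had 4 tested members, too few for a test: Cd74, the invariant chain, rose by 1.62, H2-Oa by 0.87 and H2-DMb1 by 0.68. Of its untested members, H2-Aa had 0 reads in all GFP libraries and 1 in all TDP43-NLS libraries, and Ciita 9 and 2. H2-Ab1 and H2-Eb1 were not found by name among the genes with a read. The 3 increases therefore do not show a rise of class II molecules.

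The complement list moved both ways. Of 11 tested members 5 rose and 3 fell (the same adjusted over the list alone). C5ar1 and C3ar1, receptors for complement fragments, rose by log2 fold changes of 1.99 and 1.43, Cfp, the activator properdin, by 1.87, and the central component C3 by 1.69. C3 lies in the distal part of chromosome 17. Camera called the list higher (adjusted p = 7.07e-05, adjusted p = 0.0869 with an estimated correlation), while its median log2 fold change was -0.17. Among lists without a camera call, the inflammasome list had 7 higher and 3 lower of 15, the same adjusted over the list alone. Its camera adjusted p was 0.388. Il1b rose by 3.99, Nlrc4, in the distal part of chromosome 17, by 1.11 and Nlrp3 by 0.71. Casp1, on the proximal part of chromosome 9, fell by 0.78. Nucleic acid sensing had 9 higher and 5 lower of 19 (10 and 5 adjusted over the list alone, camera adjusted p = 0.875). Ikbke rose by 0.96 and Ifi204 by 0.58, and Cgas and Myd88, both on chromosome 9, fell by 0.70 and 0.60.

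Lists of cell stress and metabolism were higher as well. Glycolysis and hypoxia genes had 27 higher and 4 lower of 36 (28 and 4 adjusted over the list alone; median log2 fold change 0.32, camera adjusted p = 6.44e-08, adjusted p = 0.0869 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase on chromosome 12, rose by 3.04, the glucose transporter Slc2a1 by 1.32, the oxidase Ero1a by 1.28 and the hexokinase Hk3 by 1.15. The unfolded protein and integrated stress response list had 21 higher and 8 lower of 34 (the same adjusted over the list alone; median 0.21, camera adjusted p = 0.000771, adjusted p = 0.0869 with an estimated correlation). Of its leading genes, Chac1 rose by 2.22, the cystine transporter Slc7a11 by 1.95, Trib3 by 1.52 and Asns, asparagine synthetase, by 0.99. Ferroptosis and iron handling had 11 higher and 4 lower of 16 (the same adjusted over the list alone; median 0.35, camera adjusted p = 0.00152, adjusted p = 0.0869 with an estimated correlation), with the iron transporter Slc11a2 up by 0.93 and the ferritin chain Fth1 by 0.74. NRF2 and oxidative stress genes had 19 higher and 6 lower of 29 (the same adjusted over the list alone; median 0.26, camera adjusted p = 0.0115, adjusted p = 0.102 with an estimated correlation). Cat, catalase, rose by 0.86 and G6pdx by 0.75, and Gclc, an enzyme of glutathione synthesis on chromosome 9, fell by 0.80.

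Apoptosis regulators had 13 higher and 3 lower of 23 (the same adjusted over the list alone; median log2 fold change 0.19, camera adjusted p = 0.0400, adjusted p = 0.139 with an estimated correlation). They moved in opposing functions: Bik and Bmf, which promote apoptosis, rose by 3.62 and 1.39, and Bcl2l1, which opposes it, rose by 1.27. The call ended when genes on chromosomes 9, 12 and 16 were left out (adjusted p = 0.0537), an alternative chosen after seeing the data. The p53 target list had 12 higher and 5 lower of 22 (the same adjusted over the list alone). Camera did not call it (adjusted p = 0.103), but did without the low-count filter (adjusted p = 0.0210). Cdkn1a, a cell cycle inhibitor, rose by 2.25, Sesn2 by 1.01 and Mdm2 by 0.59, and Sesn1 fell by 1.20.

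Lists were also lower: 3 of them passed camera. Cholesterol and fatty acid synthesis had 20 genes lower and 3 higher of 30 (22 and 3 adjusted over the list alone; median log2 fold change -0.25, camera adjusted p = 9.44e-05, adjusted p = 0.0869 with an estimated correlation). The sterol enzyme Cyp51 fell by 0.97 and Insig1, a sterol sensor, by 0.66, and Sc5d, another sterol enzyme, which lies on chromosome 9, fell by 0.79. RNA-binding and stress granule proteins had 23 lower and 3 higher of 32 (25 and 3 adjusted over the list alone; median -0.20, camera adjusted p = 0.00710, adjusted p = 0.109 with an estimated correlation). Fmr1, a translational repressor, fell by 0.63, Hnrnpa1 by 0.40, Hnrnpa3 by 0.37 and the helicase Ddx3x by 0.35. Cell cycle and DNA replication genes had 28 lower and 7 higher of 46 (the same adjusted over the list alone; median -0.19, camera adjusted p = 0.0279, adjusted p = 0.139 with an estimated correlation). Ccna2, a cyclin of S phase and mitosis, fell by 0.46, the replicative helicase subunit Mcm6 by 0.43 and the mitotic kinesin Kif23, on chromosome 9, by 0.61. Ccnd1, the cyclin of G1, rose by 0.63.

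**Figure D2:**
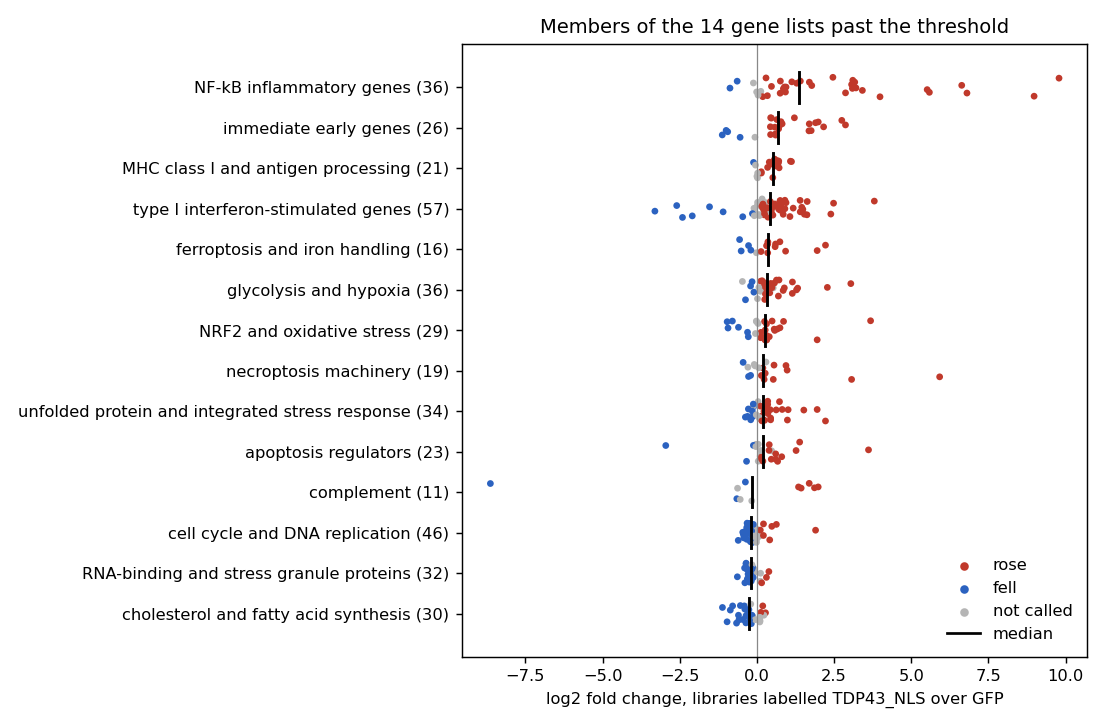
Log2 fold change (horizontal axis) of every tested member of the 14 lists past the camera threshold, with the number of tested members in brackets, red points for genes that rose, blue for genes that fell, grey for genes not called, and a black bar at the median. The median of the NF-kB list is 1.35, and the complement list has its median below 0 although camera called it higher.

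Microglial identity lists moved both ways and were not called by camera. Of 19 homeostatic microglial genes 12 fell and 6 rose (the same adjusted over the list alone, camera adjusted p = 0.258). Mertk, a receptor for the uptake of dying cells, fell by 2.97 and Tgfbr1 by 0.78, while Itgam and Selplg, both adhesion genes, rose by 1.30 and 0.76. Of 29 disease-associated microglial genes 15 fell and 8 rose (the same adjusted over the list alone, camera adjusted p = 0.792). Cd52 rose by 3.08 and Spp1, osteopontin, from 1245 to 4452 CPM (log2 fold change 1.84), whereas Cst7 and Clec7a fell by 1.65 and 1.42. For this list camera pointed lower and fry higher, neither with a call. Of 36 phagocytosis and lysosome genes 18 rose and 13 fell (19 and 13 adjusted over the list alone, camera adjusted p = 0.695). The scavenger receptor Cd36 rose by 2.83 and Fcgr2b by 1.10, and Atp6v0d2, a proton pump subunit, fell by 3.86. The median of that list was 0.12, its mean -0.12, and the direction given by camera higher. By fry the phagocytosis and lysosome list was called higher (adjusted p = 1.64e-05) and the homeostatic list lower (adjusted p = 0.00314).

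The remaining lists were not called by camera. Of 24 reported RNA targets of TDP-43, 9 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.336). Spata13 rose by 1.72, Pfkp by 0.71 and Grn, progranulin, by 0.33, and Tecpr1 fell by 0.38. Cytosolic heat shock genes had 8 lower and 3 higher of 17 (9 and 3 adjusted over the list alone, adjusted p = 0.227), with Hsf1 down by 0.56, Chordc1, on chromosome 9, by 0.51, Hspd1 by 0.28 and Stip1 by 0.26. Nuclear genes of oxidative phosphorylation had 11 lower and 5 higher of 38 (11 and 4 adjusted over the list alone, adjusted p = 0.305). Sdhd and Uqcrc1, on chromosome 9, fell by 0.71 and 0.26, and Uqcrfs1 and Ndufs1 by 0.29 and 0.28. Without GFP replicate 2, the library that stood apart, this list was called lower (adjusted p = 0.0184). Of 12 mitochondrially encoded genes 5 fell and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 0.324), and they moved apart: mt-Cytb fell by 0.71, mt-Nd3 by 0.56 and mt-Nd2 by 0.26, and mt-Co1 rose by 0.26. The call of mt-Nd3 was lost without TDP43-NLS replicate 2 (adjusted p = 0.0683) and with DESeq2 (adjusted p = 0.115). Ribosomal protein genes had 17 higher and 2 lower of 42 (the same adjusted over the list alone, adjusted p = 0.324), with Rps20, Rpl5, Rps24 and Rplp0 up by 0.42, 0.39, 0.23 and 0.20. Proteasome and autophagy genes had 11 higher and 7 lower of 32 (the same adjusted over the list alone, adjusted p = 0.539). The autophagy receptor Sqstm1 rose by 0.81 and Wipi2 by 0.46, Psmc1, on chromosome 12, rose by 0.31, and Psma4, on chromosome 9, fell by 0.37. Replication-dependent histones had 4 higher and 2 lower of 17 (the same adjusted over the list alone, adjusted p = 0.837): H4c9 and H3c8 fell by 1.03 and 1.02, and H1f3 and H1f2 rose by 0.57 and 0.29. Their median was 0.29 and their mean 0.05, camera pointed lower and fry higher.

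Most markers of other cell types had too few reads to be tested. The neuron, astrocyte, and lymphocyte and granulocyte lists had 1 tested gene each, the oligodendrocyte list 4, and the fibroblast and epithelial list none. Tubb3 rose from 0.273 to 1.04 CPM, Cspg4, on chromosome 9, from 0.740 to 1.63 CPM, Cnp from 35.9 to 44.8 CPM and Aldoc, which the glycolysis list also holds, from 128 to 144 CPM, and Cd4 fell from 0.915 to 0.160 CPM.

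As a limit of the list results, camera with its preset correlation also called up to 12 lists in other splits of the 6 libraries, which hold part of the real difference. Of the 14 lists called here, the NF-kB and immediate early lists were called in all 9 other splits and the interferon, glycolysis and cholesterol lists in 8. The RNA-binding list was called in 7, MHC class I in 6, the cell cycle list in 5, the apoptosis and NRF2 lists in 2, the necroptosis list in 1, and the complement, ferroptosis and unfolded protein lists in 0. By fry, 16 of the 27 lists went on balance higher, 5 lower, and 26 held genes changed in either direction. Fry does not compare a list with other genes, and 57.6% of all tested genes were called. Most lists were therefore likely to hold changed genes from the start, and a call by fry does not set a list apart from other genes. Of lists that camera did not call, fry called the reported TDP-43 target (adjusted p = 0.000154), p53 target (0.000126) and inflammasome (0.000239) lists higher. It also called the phagocytosis and proteasome lists higher, and the homeostatic and heat shock (adjusted p = 0.00187) lists lower. The test against a log2 fold change of 0.5 also ended the calls of H2-Oa, Ifi204, Mdm2, Hnrnpa1, Hnrnpa3, Ddx3x, Ccna2, Mcm6, Grn, Tecpr1, Hsf1, Chordc1, Hspd1, Stip1, Uqcrc1, Uqcrfs1, Ndufs1, mt-Nd3, mt-Nd2, mt-Co1, Wipi2, Psmc1, Psma4, H1f3, H1f2, Cnp, Aldoc and the 4 named ribosomal protein genes.

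Terms of the deposited Gene Ontology annotation were tested apart from the fixed lists. Among genes that rose, 84 of 2614 terms were enriched, and among genes that fell, 4 (one-sided Fisher's exact test, Benjamini-Hochberg adjusted). Inflammatory response had 102 of 197 genes higher against 59.5 by chance (adjusted p = 4.09e-07), neutrophil chemotaxis 21 of 28 against 8.46 (adjusted p = 0.000464), and chemokine-mediated signalling 13 of 14 against 4.23 (adjusted p = 0.000503). The cellular response to hypoxia had 44 of 82 higher (adjusted p = 0.00174), and apoptotic signalling from endoplasmic reticulum stress 20 of 29 (adjusted p = 0.00392). The terms lower were negative regulation of mRNA splicing, with 22 of 33 genes against 9.48 by chance (adjusted p = 0.00159), chromatin binding, with 146 of 393 (adjusted p = 0.0159), RNA splicing, with 68 of 167 (adjusted p = 0.0393), and DNA methylation, with 13 of 20 (adjusted p = 0.0483). None of the 4 was enriched among genes lower by a log2 fold change of at least 1, where 13 other terms were. Among genes higher by at least that much, hypoxia (adjusted p = 0.250) and the endoplasmic reticulum stress term (adjusted p = 1) were not enriched. Leaving out a library ended some calls: without TDP43-NLS replicate 3 the adjusted p was 0.0721 for the endoplasmic reticulum stress term, 0.0650 for chromatin binding, 0.157 for RNA splicing and 0.109 for DNA methylation, and without GFP replicate 2 it was 0.0592 for RNA splicing and 0.0611 for DNA methylation. RNA splicing was also lost without GFP replicate 3 (0.0545), TDP43-NLS replicate 1 (0.0503) and TDP43-NLS replicate 2 (0.0569).

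Fold changes also followed the chromosomes, a comparison added after seeing the data. Over 9306 expressed genes, shuffling genes across chromosomes kept the largest deviation of a chromosome median within 0.06 in 95% of 10000 shuffles, and 10 chromosomes lay beyond it. Chromosome 9 had a median log2 fold change of -0.32 over 507 genes, with 80.9% of them lower, and its proximal part (3335140 to 44876898, 135 genes) had -0.54, with 89.6% lower. Chromosome 16 had -0.23 over 303 genes, chromosome 13 had -0.13 over 324, and chromosome 12 had 0.17 over 336, with 20.5% lower. The permutation p was 1e-04 for each of these 4, the smallest that the shuffles can give. The distal part of chromosome 17 (56259640 to 95057447, 121 genes) had a median of 0.31. On chromosome 5, 4 successive windows of 40 genes (52932751 to 114829045) had medians of 0.21, 0.24, 0.29 and 0.18, and the first window (3286431 to 22931166) had -0.26. Of the named genes, Cxcl2, Spp1, Rpl5 and Selplg lie in the higher part of chromosome 5 and Cfap69, Cyp51 and Cd36 in its first window, and Ripk1, Iqgap2, Hk3, Pfkp, Uqcrfs1 and the histones lie on chromosome 13.

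**Figure D3:**
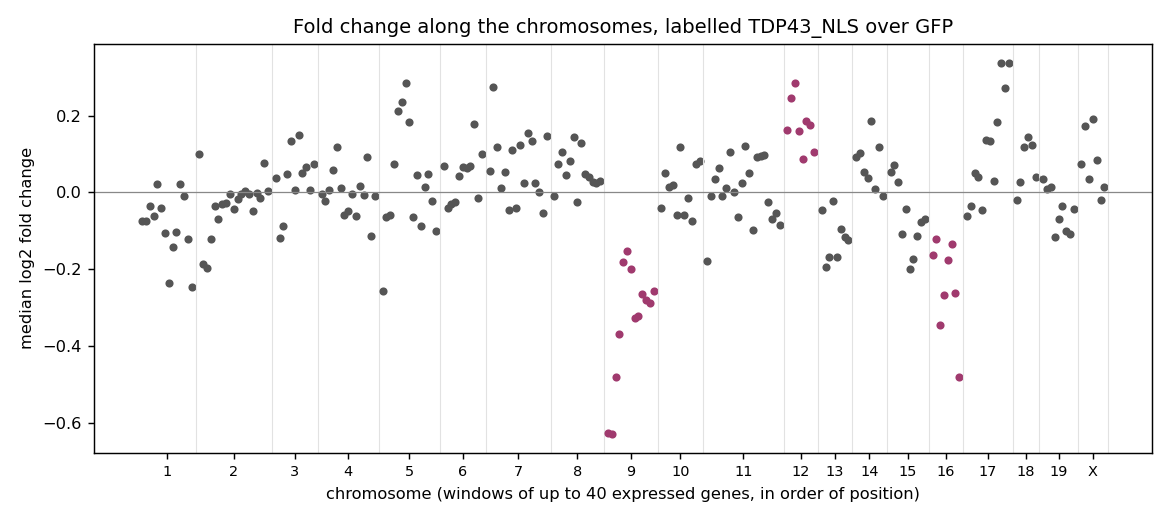
Median log2 fold change (vertical axis) of successive windows of up to 40 expressed genes along each chromosome (horizontal axis), libraries labelled TDP43-NLS over GFP, with chromosomes 9, 12 and 16 in colour. The windows of chromosome 9 lie below 0 throughout and reach -0.63 at its proximal end, and those of chromosome 12 lie above 0.

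The FPKM values gave 3019 genes higher and 3653 lower of 12710 tested (limma on log2(FPKM + 1), a scale that understates changes of low genes). Of 7011 genes called on counts and tested here, 100% had the same sign and 6255 were also called. As FPKM is computed from the same reads, this compares the tests and not separate measurements.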

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

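The alternatives that leave out genes on chromosomes 9, 12 and 16, the libraries left out of the term tests, and every alternative for chromosome medians were chosen after seeing the data. Under the 16 alternatives for the count test, no called gene of the reported fit was called with the opposite sign. Only the test against a log2 fold change of 0.5 moved the counts of calls by over 1.5 times, to 1226 higher and 749 lower, as that test asks for larger changes, and it ended the call of Tardbp at its log2 fold change of -0.26. Without each library in turn, 3523 to 4208 genes were higher and 3191 to 4048 lower, both highest without GFP replicate 2, and Tardbp ranged from -0.31 to -0.23. By library totals alone 45.1% of the calls were higher, against 50.9% as reported. With DESeq2 3187 were higher and 3085 lower. Without genes on chromosomes 9, 12 and 16, 3347 were higher and 3175 lower. Of 1980 repeats of 132 named genes, 1945 kept the call and direction, 35 lost the call and 0 reversed. Most of these genes were named for a large or significant change in the same libraries, so kept calls were likely from the start. All the losses came from the test against 0.5 except for mt-Nd3, which also lost its call with DESeq2 and without TDP43-NLS replicate 2.

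The replicate numbers do not pair the libraries: the deviations of same-numbered libraries from their group means correlated at -0.02, -0.01 and 0.00 across genes. With the replicate number as a block, 3855 genes were higher and 3692 lower. The block changed no list call, and Tardbp stayed at -0.26.

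For the lists, camera with an estimated correlation left 1 higher and 0 lower, and fry gave 16 higher and 5 lower. The estimate was under the preset 0.01 for the unfolded protein (-0.0235), ferroptosis (-0.0301), apoptosis (-0.0359) and NRF2 (-0.0147) lists. The same held for the cholesterol, RNA-binding and cell cycle lists. For these lists a larger correlation therefore does not account for the lost call. It was above 0.01 for the other lists called as reported, such as MHC class I (0.119). The cause was not tested further. Across alternatives the adjusted p of the necroptosis list ranged from 4.82e-05 to 0.137 and that of the NF-kB list from 5.68e-83 to 0.00563. Without each library, 11 lists were higher each time and 3 to 4 lower. The number of lower terms was 13 with calls of a log2 fold change of at least 1, 8 with all tested genes as background, 7 to 12 without each library and 9 without the 3 chromosomes, against 4 as reported. The cause was not tested. Without the 3 chromosomes the adjusted p was 0.0564 for the endoplasmic reticulum stress term, 0.151 for DNA methylation and 0.0537 for the apoptosis list, each then without a call. On FPKM, the counts stayed within 1.5 times. The median of chromosome 9 ranged from -0.35 by library totals to -0.30. Depth limits genes with few reads, such as Zbp1, for which no direction can be given.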

Other observations

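The tests of a mislabelled library, of copy number around Tardbp, of exchanged labels and of sequencing depth, and the whole comparison by chromosome, were chosen only after the result was seen.

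Further annotation terms, which can share genes with the fixed lists, were enriched among strongly changed genes. Among genes higher by a log2 fold change of at least 1, 17 of 54 cytokine genes were found against 3.31 by chance (one-sided Fisher's exact test, adjusted p = 4.80e-06), and 11 of 32 inhibitors of serine proteases against 1.96 (adjusted p = 0.000360). G-protein coupled receptor signalling was enriched in both directions, with 21 of 112 genes higher by at least that much (adjusted p = 0.000670) and 15 lower (adjusted p = 0.000552). Chosen after their values were seen, Axl, a receptor for dying cells like Mertk, fell by 4.10 on the log2 scale, and Ifih1, a sensor of double-stranded RNA, by 3.31, while Myc rose by 1.90 among cell cycle genes that mostly fell.

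Tardbp was lower in the libraries labelled as overexpressing TDP-43. The choice among 5 scalings and tests did not matter, as the highest log2 fold change over them was -0.26. They moved the median log2 fold change of the tested genes only between -0.034 by library totals and 0.005 by limma-voom. None could thus have brought Tardbp to 0. All of them take total or typical expression as equal, so a difference in RNA content per cell was not examined. A single library in the wrong group is argued against, as every library correlated better with its own group, by at least 0.0251 in mean Spearman correlation, and a shift of the whole locus is too, as the 40 expressed genes around Tardbp had a median of 0.0317. Exchanged labels of the whole groups cannot be told apart from the labels as given: the fold change would then be 0.26, and no marker of either construct is among the counted genes. TDP-43 is known to lower its own messenger RNA, so a construct whose reads were not counted on the mouse gene is another candidate explanation, which was not tested.

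Chromosome 9 was lower as a group. Of its 507 genes 80.9% were lower, so the shift was not that of a few strong genes. Without called genes of an absolute log2 fold change of at least 1 the median was -0.31. That left 493 genes, too many for a median to move far, so this removal could not decide the question. The median stayed at -0.31 after a trend on GC content and length was removed, and at -0.32 without GFP replicate 2. These 2 values argue against base composition and that library. If the cells labelled TDP43-NLS had fewer copies of the region, genes of every kind should be lower there. The 20 tested non-coding genes and pseudogenes of its proximal part had a median 0.48 lower than elsewhere on the log2 scale (difference -0.48, 95% bootstrap interval -0.81 to -0.17), with 80% of them lower. This is consistent with a hypothesis that the groups differ in chromosome copies, as populations of a cell line that grew apart may do. In that case part of the difference between the groups may be a difference between cell populations and not an effect of the construct. Expression data alone do not settle it. The use of strand in counting is not given, so some of the 20 genes may hold reads of overlapping coding genes. The bootstrap interval also takes neighbouring genes as independent. The proximal part was marked off after the fold changes by chromosome were seen in these same libraries. Non-coding genes above the expression limit were among the genes that showed it to be low. A low median of the 20 genes was therefore partly given from the start. Non-coding genes of the rest of chromosome 9 were not compared.

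The 85 genes changed by a log2 fold change of at least 4 went both ways. Of them, 57.6% were lower in the GFP group, which had fewer reads. The group totals were 49395151 reads for GFP and 50679537 for TDP43-NLS. Totals this close do not account for changes of this size, and for the same reason the 57.6% could not test depth. The 5 expressed genes on either side had a median log2 fold change, signed by the gene's direction, of 0.0480 in the median case. The quartiles were -0.11 and 0.20, and 0 of the 85 reached 1. This argues against loss or gain of a stretch of chromosome that holds most of these neighbours. A shorter one, with the gene and few expressed neighbours, would not move such a median and cannot be seen this way. Short losses or gains may remain for some of the 85 genes. Switching of single genes, by the construct or by divergence of the cell populations, may remain for Ripk3 and Ppfibp2 among others. These possibilities were not tested apart.

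The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave as many results. The count test called 7605 genes in the real split and at most 0 in another, and limma on FPKM 6672 and at most 0. Camera called 14 lists in the real split and up to 12 in another, where NF-kB, immediate early and ribosomal protein genes were called in all 9. Each other split puts 2 libraries of a group with 1 of the other and so holds part of the real difference. With an estimated correlation the numbers were 1 and 0, and with fry 21 and 0. In the other splits the real difference also widens the spread within each set of 3 libraries. The gene tests, fry and camera with an estimated correlation were therefore likely to call little there. Their values of 0 do not measure how often chance gives calls.

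GFP replicate 2 deviated from the other GFP libraries in a way that followed gene length. Across 9320 expressed genes, which are not independent replicates, Spearman's rho of its deviation with length was 0.372, and with GC content 0.0667 across 9311.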
